A study of Homo sapiens with 2 samples.

How the data were processed

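HMGA1, a chromatin protein whose AT hooks bind the minor groove of AT-rich DNA, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in IMR90 human diploid fibroblasts. Per the labels' protocols, cells at population doublings 25 to 35 were kept in low oxygen (2%), infected with a RAS or an empty-vector retrovirus on days 1 and 2, put under puromycin (1 µg/ml) on day 3 and harvested after a further 9 days, on day 12 of the experiment. The immunoprecipitation used 5 µg of an antibody to HMGA1, and libraries were made from 10 ng of DNA with 12 cycles of PCR. There was 1 library per group, RAS and vector, so no value has an error between replicates and no test between the conditions was possible.

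Per the submitters' processing notes, Bowtie 0.12.9 and HOMER were used with the human build hg19. The HOMER version, its settings and any use of input DNA are not given in the sources used here. The deposited table was a peak list, with 1 row per peak, and its name reads RAS versus vector. No column named a library, so the peak-called library was read as RAS and the control as vector from that name. Per the file headers, the authors' table gave the RAS signal as a tag count scaled to 10000000 tags, the RAS tags scaled to the depth of the vector library, the vector tags (signal), the fold of RAS over vector (ratio), a fold over the local surroundings, a p-value for each fold, a findPeaks score, a focus ratio (the fraction of tags on the side of the centre where a point source puts them) and a fold for clonal tags. Every fold and score was the peak's own value, set by the authors' peak caller.

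The limits that the list met were read from its values. The fold over vector was 4.02 or more and the fold over the local surroundings 4 or more. The p-value over vector was at most 7.14e-05 and that over the surroundings at most 3.41e-05. The deposited folds equalled scaled RAS tags divided by vector tags within 1% in 100% of peaks, with 0.5 in place of a vector count of 0. The p-value over vector equalled the upper tail of a Poisson law with the vector tags as its mean, within 5%, in 99.1% of peaks. That calculation takes the vector count as known without error.

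Scaled RAS values rose in steps of 0.282 per 10000000 tags, and 99.7% of them were whole multiples of the step within 0.1 tag, so whole RAS tags were recovered. The step put the depth at about 35400000 tags for RAS, and the scaling factor of 0.963 put it at about 34100000 for vector. The ratio of tags at a peak was given an exact 95% interval (Clopper-Pearson, conditional on the total tags). It covers counting error in these 2 libraries only, because each group has 1 library. PCR reads without molecular identifiers are not independent molecules, so the interval may be too narrow even for counting error. For 0 vector tags the fold was taken over a floor of 3 tags per library. Local background was taken as scaled RAS tags divided by the fold over the surroundings.

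Peaks per chromosome were set against 1000 random sets drawn in proportion to the span from the first to the last listed peak. This span was used because no chromosome lengths of hg19 were used here. Neighbouring peaks were compared with 1000 sets of random positions within the same spans. Both comparisons describe these peaks, and peaks are not replicates. The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. On 2352 simulated peaks with vector rates of 4 and 8 tags, the estimate of a rate cut at the 4-fold limit returned 3.94 and 8.01. Each of those runs used a common rate for all peaks, whereas the estimated rate in the data differed with RAS tags. The exact interval held the simulated ratio in 97.4% of 1000 draws. These draws were not selected by fold, so the coverage need not hold for the listed peaks.

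The plan made before the data were examined also held genomic classes, base composition, 13 fixed gene lists, the genes nearest to peaks and the genes NAMPT and HRAS. No sequence or annotation of hg19 was used here, and the gene table used here follows another build, so peaks were assigned to no gene and these parts were not run. The gene table served only to count protein-coding genes per chromosome. By the rule fixed in that plan, the peaks named below are the 15 with the highest fold and, since the list runs in 1 direction, the 10 with the most tags, given by position. The windows of 1 Mb with 5 or more peaks and a pair of peaks on chromosome 7 were chosen after their values were seen. Alternatives were a fold of at least 8, an authors' p-value of at most 1e-10, merging peaks within 10 kb, autosomes and X only, 1 tag added to both libraries, at least 20 RAS tags, and other distances.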

Results

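HMGA1 ChIP-seq was done in IMR90 fibroblasts infected with RAS, which enter oncogene-induced senescence, a lasting growth arrest, and in growing fibroblasts infected with the empty vector. The series title ties the study to NAD+ metabolism and the inflammatory secretome of senescent cells. There was 1 library per group, of about 35400000 tags for RAS and 34100000 for vector, and the deposited data were a list of peaks. The comparison asks where on the genome HMGA1 tags were higher in RAS cells than in vector cells.

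The list held 2352 peaks, and at each of them the RAS library had more HMGA1 tags than the vector library. The peaks lay on all autosomes and X, with 1 on Y, and each spanned 366 bp from start to end. RAS tags per peak had a median of 19 (quartiles 17 and 21, range 13 to 38), and vector tags had a median of 4 (quartiles 3 and 4, range 0 to 8). The median of the authors' fold was 5.06, with quartiles of 4.34 and 6.10 and a range of 4.02 to 38.55. When the vector rate was instead estimated under the 4-fold limit, a setting chosen after seeing the data, mean scaled RAS tags were 2.37 times that rate. The RAS tags in this ratio were still selected to be high, so it is not an estimate of the gain and does not exclude equal rates. Peaks lower in RAS number 0 because the list holds only peaks above a 4-fold limit, so loss of HMGA1 in RAS cells was not analysed here. With these tag numbers, the median lower 95% limit of the RAS-to-vector ratio was 1.61, and its range over peaks was 1.15 to 4.76. These limits do not allow for the selection of every listed peak by its fold, so they do not show that each peak was higher in RAS beyond counting error. The authors' p-values reached from 7.14e-05 down to 6.18e-25 and compare these 2 libraries, not the conditions.

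**Figure D1:**
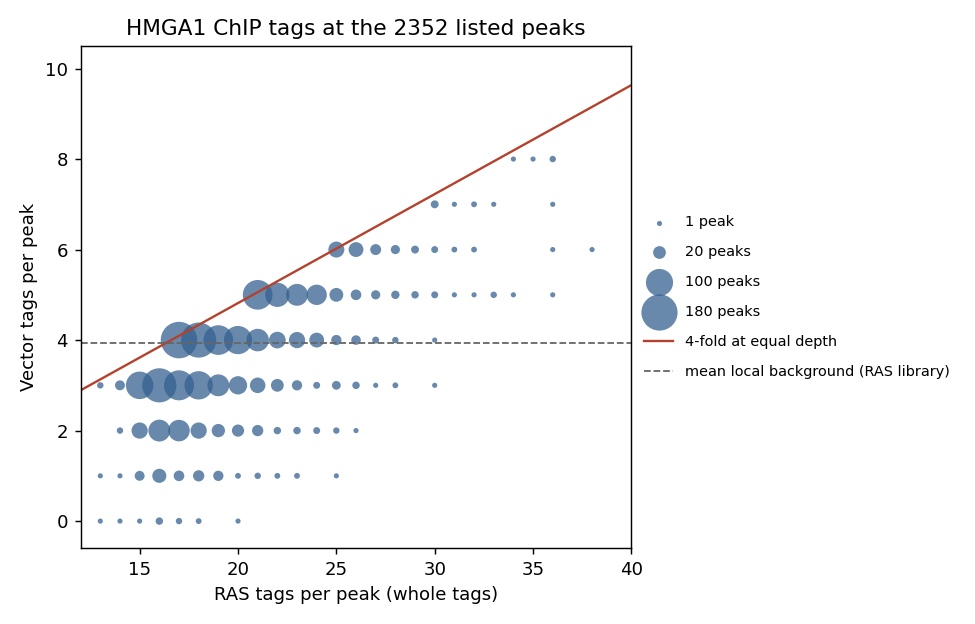
RAS tags (x axis, whole tags per peak) and vector tags (y axis, tags per peak) at the 2352 listed peaks, with point area rising with the number of peaks at that pair of values, a red line at 4-fold and a dashed line at the mean local background of 3.93 tags. Peaks crowd under the red line, and 1280 of them have the most vector tags that the 4-fold limit allows.

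Of the 2352 peaks, 1151 had a fold from 4 to under 5, 913 a fold from 5 to under 8 and 288 a fold of 8 or more, of which 22 reached 20. Across peaks, which are not independent replicates, the fold over vector and the fold over the local surroundings had a Spearman's rho of -0.01. Both folds share the RAS tags and both had passed a 4-fold limit, so this rho does not show how they relate beyond the list. The median fold over the surroundings was 4.61 (quartiles 4.25 and 5.26), which puts the local background in the RAS library at a median of 3.84 tags per peak width after scaling to the vector depth. The vector tags at the same peaks had a mean of 3.61, a value that the 4-fold limit holds down. The vector rate estimated under that limit was 7.97 tags, 2.03 times the mean local background, which the 4-fold limit on the local fold holds down in turn, and above the average of 4.37 tags per peak width over the spans. The focus ratio had a median of 0.731, and the clonal fold lay between 0.95 and 0.98.

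The highest fold was at chromosome 22, 40140492 to 40140858 (hg19), where RAS had 20 tags and vector 0. Its scaled RAS tags were 6.42 times a floor of 3 tags, and the exact lower 95% limit of its ratio, which also counts error in the RAS tags, was 4.76. In the authors' deposited table its fold was 38.55. Of the 15 peaks with the highest fold, 14 had 0 vector tags and between 13 and 20 RAS tags, 4.18 to 6.42 times the floor, with exact lower limits of 2.94 to 4.76. Chromosome 2, 171723290 to 171723656, and chromosome 3, 145924736 to 145925102, each had 18 RAS tags, with a lower limit of 4.24. Chromosome 1, 221936269 to 221936635, chromosome 8, 120236331 to 120236697, and chromosome X, 129946477 to 129946843, each had 17 tags, with a lower limit of 3.98. A further 5 peaks had 16 tags each, with a lower limit of 3.72. They started at 48845307 on chromosome 1, at 60629513 and 83803501 on chromosome 10, at 32094773 on chromosome 15 and at 33037482 on chromosome 21. Peaks starting at 210280882 on chromosome 1, at 57777101 on chromosome 13 and at 113415198 on chromosome 4 had 15, 14 and 13 tags. The remaining peak, chromosome X, 139967168 to 139967534, had 25 RAS tags and 1 vector tag, a ratio of 24.09 with an exact 95% counting interval of 3.94 to 989. The 15 peaks were spread over 11 chromosomes. The folds divide by vector tags, with 0.5 for 0, so peaks with 0 vector tags lead the ranking by construction. The limits and intervals of all peaks named here cover counting error only and do not allow for the choice of these peaks by their fold or tags.

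Among listed peaks, those with the most RAS tags were other sites with lower folds. Sites with more RAS tags that did not pass the filters are not on the list. The 10 with the most tags and the 15 with the highest fold had 0 peaks in common. Chromosome 2, 212706437 to 212706803, had the most, with 38 RAS tags and 6 vector tags, a ratio of 6.10 (exact 95% counting interval 2.56 to 17.7). Chromosome 10, 47120900 to 47121266, had 36 and 5 tags, a ratio of 6.94 (2.71 to 22.6). Chromosome 11, 10215246 to 10215612, had 36 and 6 tags, a ratio of 5.78 (2.41 to 16.8). Chromosome 8, 54200908 to 54201274, had 36 and 7 tags, a ratio of 4.96 (2.17 to 13.2). The peaks starting at 16936019 on chromosome 1, at 57751848 on chromosome 10 and at 111597719 on chromosome 8 had 36 and 8 tags each, a ratio of 4.34 (1.98 to 10.8). The peak starting at 27951353 on chromosome 4 had 35 and 8 tags, that starting at 4425286 on chromosome 10 had 34 and 5, and that starting at 8153439 on chromosome 16 had 34 and 8. The 10 peaks lay on 7 chromosomes.

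**Figure D2:**
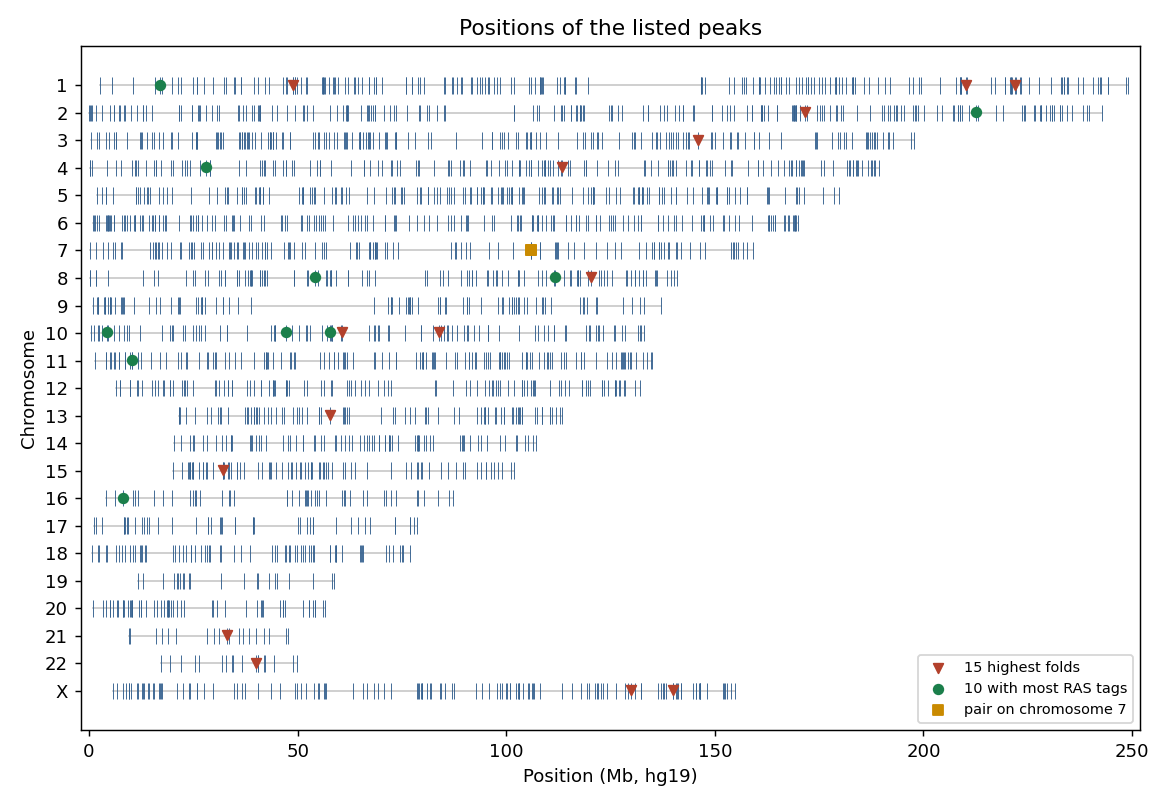
Start positions (x axis, Mb in hg19) of the listed peaks on chromosomes 1 to 22 and X (y axis), with each peak as a tick, the 15 highest folds as triangles, the 10 peaks with the most RAS tags as circles and the chromosome 7 pair as a square. Peaks are spread along all chromosomes, and 0 peaks carry both the fold mark and the tag mark.

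A pair of peaks on chromosome 7 was looked at because the series title names NAD+ metabolism and NAMPT, the enzyme that limits the making of NAD+ from nicotinamide, is known to lie in this part of chromosome 7. No hg19 annotation was used here, no distance to the gene was measured and the peaks were not assigned to it. The peak at 105927232 to 105927598 had 16 RAS tags and 1 vector tag, a ratio of 15.42 (exact 95% counting interval 2.39 to 646). The peak at 105945664 to 105946030, 18432 bp further on, had 17 RAS tags and 3 vector tags, a ratio of 5.46 (1.58 to 29.1). Of all peaks, 89 had a fold at least as high as the first of the pair, and 46 of 2328 neighbouring pairs on the list lay as close to each other. The pair was chosen after its values were seen, and both peaks were on the list because their fold passed 4, which the intervals do not allow for.

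Relative to span, peaks were thinner on chromosomes 16, 17 and 19 than in random sets. Over chromosomes 1 to 22 and X there were 0.819 peaks per Mb of span. Chromosome 19 had 0.469 per Mb (22 peaks, exact 95% Poisson interval 0.294 to 0.710 per Mb), and its first listed peak started at 11868970. Chromosome 16 had 0.566 per Mb (47 peaks, 0.416 to 0.753), and chromosome 17 had 0.569 per Mb (44 peaks, 0.414 to 0.764). Chromosome 9, at 0.639 per Mb, and chromosome 21, with 19 peaks against 31.2 expected from its span, also lay below the middle 95% of 1000 random sets. Chromosome 6 lay above it, at 1.02 per Mb (173 peaks, 0.877 to 1.19). Chromosome X, at 0.879 per Mb, lay within the random range, as did 17 of the 23 chromosomes in all. Random sets put a median of 1 chromosome outside its range, and the middle 95% of sets reached up to 3. When the longest stretch without a peak was taken out of each span, 3 chromosomes lay outside, which were 16, 17 and 19, and among the 288 peaks with a fold of 8 or more 0 did. In another setting, expected counts followed the highest running number in each chromosome's peak identifiers in place of its span. Chromosomes 16 and 17 then lay above their range, 6, 9 and 19 lay within it, and 21 stayed below. Chromosomes 4, 8 and 13 also came to lie below, and 1, 11, 15, 20 and 22 above.

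**Figure D3:**
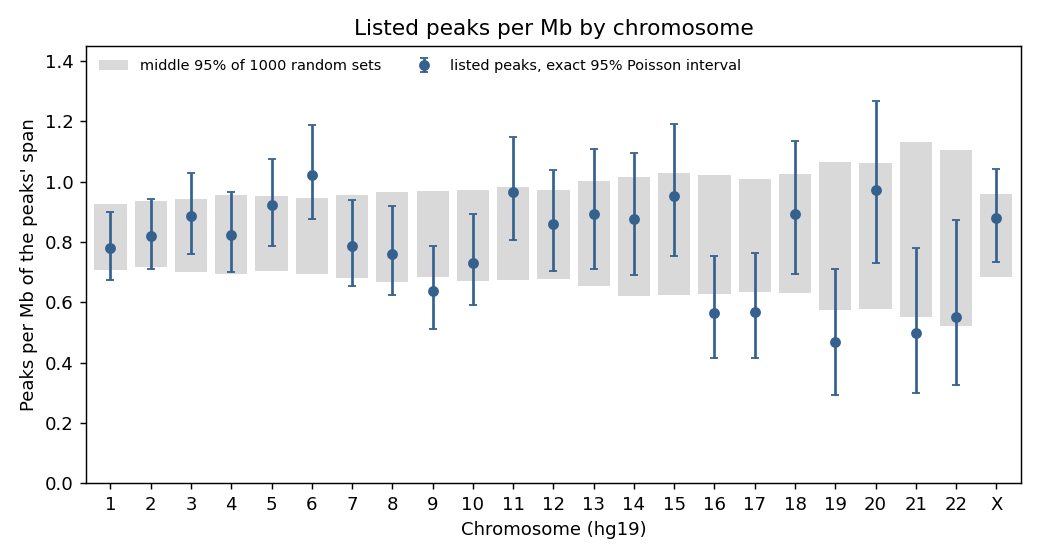
Listed peaks per Mb (y axis) by chromosome in hg19 (x axis), with points for the peaks, bars for exact 95% Poisson intervals that cover counting error only, and grey boxes for the middle 95% of 1000 random sets. Chromosomes 9, 16, 17, 19 and 21 lie below their boxes and chromosome 6 above its box.

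Listed peaks were scattered and not gathered in clusters beyond the random range. Each had passed a 4-fold limit over its own surroundings, which can remove neighbouring peaks and which the random positions did not face. The comparison therefore describes the list and cannot show whether sites were clustered before that filter. The median distance between neighbouring peaks was 788 kb, and the smallest was 1577 bp. Of 2351 peaks on chromosomes 1 to 22 and X, 44 (1.87%) had another peak within 10 kb, against a random median of 1.62% with a middle 95% of 0.936% to 2.42%. Within 100 kb the share was 16.97%, against 15.3% (13.4% to 17.1%). The number of windows of 1 Mb with 5 or more peaks was 5, which was also the median of random sets (1 to 9). The fullest was on chromosome 15 from 24 to 25 Mb, with 6 peaks that summed to 111 RAS tags and 24 vector tags, a ratio of 4.46 (exact 95% counting interval 2.85 to 7.25). On chromosome 6 the windows from 4 to 5 Mb and from 169 to 170 Mb held 5 peaks each, with ratios of 4.82 (2.92 to 8.35) and 5.18 (3.01 to 9.46). The windows from 108 to 109 Mb on chromosome 1 and from 68 to 69 Mb on chromosome 7 also held 5, with ratios of 4.78 (3.03 to 7.84) and 4.77 (2.89 to 8.27). Summed tags at peaks picked for a fold above 4 give ratios above 4 by selection.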

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

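Merging peaks within 10 kb left 2329 regions with the same median fold of 5.06 and the same number of chromosomes outside the random range, and autosomes with X gave 2351 peaks. Asking for a fold of at least 8 left 288 peaks, and an authors' p-value of at most 1e-10 left 400. Among the 288, 0 chromosomes lay outside the random range and 0% of peaks had a neighbour within 10 kb; with 288 peaks the random ranges are wider. Counting error in the vector library was chosen as an alternative after seeing the data: a one-sided exact conditional binomial p of at most 1e-4 left 235 peaks, and a lower limit of the tag ratio of at least 2 left 352. The median fold was 4.82 at peaks with at least 20 RAS tags and 4.10 with 1 tag added to both libraries. In place of a median, the ratio of mean scaled RAS tags to a vector rate estimated under the 4-fold limit, also added later, was 2.37; its RAS tags were still selected to be high, so it does not exclude equal rates. The share of peaks with a neighbour was 0% within 1 kb and 16.97% within 100 kb, since a longer distance takes in more neighbours. Random sets had a median of 0.17% within 1 kb (middle 95% 0% to 0.425%), without the limit on the local fold that the listed peaks had passed. The number of chromosomes outside the random range, 6 as reported, was 3 without the longest stretch free of peaks and 11 when expected counts followed the highest peak number on each chromosome, both added later. In the latter, chromosomes 16 and 17 turned from below to above their range, 6, 9 and 19 came to lie within it, and 21 stayed below. The alternatives planned for genomic class, base composition, gene lists and NAMPT, and the one that leaves out peaks at HRAS, were not run, since no hg19 annotation or sequence was used here. No paired analysis was possible because each group has 1 library, and for the same reason no replicate could be left out. Depth limits every peak: with a median of 19 against 4 tags, the lower 95% limit of the ratio stayed under 2 at all but 352 of the 2352 peaks.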

Other observations

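All tests in this part were chosen after the values they bear on had been seen. The peak identifiers carry a running number per chromosome that rises as the score falls, with a Spearman's rho across peaks between -0.995 and -0.977 on single chromosomes. Read as the rank of a peak among all candidates called in the RAS library, these numbers give at least 210296 candidates on chromosomes 1 to 22 and X, of which at most 1.12% are on the deposited list. Each chromosome's highest number is a lower bound on its candidates, and it rests on few listed peaks where few are listed (18 on chromosome 22, 156 on chromosome 4). Divided by the span of the listed peaks, the highest numbers gave 117 and 110 candidates per Mb on chromosomes 13 and 4. On chromosomes 22, 19, 17 and 16 they gave 20.7, 26.7, 34.1 and 36.3. The span is shorter than the chromosome, which raises these quotients, so they are not lower bounds on candidates per Mb. The quotients had a 5.65-fold range, and listed peaks per Mb of the same spans a 2.18-fold range.

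Candidate density, taken as these quotients, was lower on chromosomes with more genes per Mb, a relation noticed in these data and not tested on others. Gene density was the number of protein-coding genes on the whole chromosome, from a table of another build, divided by the span of the listed peaks, which overstates it where the span is short, as on chromosome 19. Over 23 chromosomes, Spearman's rho between protein-coding genes per Mb and candidates per Mb was -0.85 and Pearson's r -0.71, each with a permutation p of 1e-05, the smallest that the permutations can give (2e-05 after Benjamini-Hochberg adjustment over 2 relations). Without chromosomes 17 and 19, which lie farthest from the median gene density, r was -0.84 and rho -0.81 (permutation p = 5e-05). For the listed peaks, r was -0.56 (p = 0.0028) and rho -0.32 (p = 0.13, permutation tests), and r fell to -0.29 without the same chromosomes, so that relation rests on them. Whether the candidates follow AT-rich DNA bound by HMGA1, or a GC bias of the PCR-amplified libraries, was not tested, since no hg19 sequence was used here and an input library was not analysed.

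The vector tags at listed peaks pile up at the limit that the 4-fold filter sets: 1280 of 2352 peaks (54.4%, Wilson 95% interval 52.4% to 56.4%) had the most vector tags that the filter allows. If every listed site were at background in vector cells, a Poisson law cut at the limit would give a rate near the local background, 3.93 tags in the RAS library at the vector depth. The estimated rate was 7.97 tags (bootstrap 95% interval 7.62 to 8.35), 2.03 times that background. Intervals in this paragraph are over listed peaks, which are not replicates, and hold no variation between libraries. The local background is itself held down by the limit on the local fold, so it may be too low a standard. The rate also lay above the average over the spans, 4.37 tags per peak width. That average is over all positions, whereas listed sites were picked for high RAS tags, and their local background ranged from 0.805 to 8.53 tags. The comparison therefore cannot exclude background level at all sites, and a mix of sites at background and others above it also stays open. The rate rose from 6.84 at peaks with 13 to 16 RAS tags to 10.2 at those with 26 to 38, and the local background rose with it, from 3.21 to 5.42, so the rise itself says nothing more. A second candidate explanation is chance selection: among candidates with equal rates in both libraries, some draw few vector tags. A gamma-Poisson model fitted to the candidate scores, with no difference between the libraries, put 1860 candidates with scores under 21 past the 4-fold limit, where 1399 are listed, so equal rates may account for a list of this size there. That surplus comes from scores 16 to 18: at 19 and 20 the listed peaks, 263 and 192, already outnumber the predicted 241 and 138. The model also gave a mean of 3.30 vector tags past the limit, below the observed 3.61 (bootstrap 95% interval 3.56 to 3.65). The most vector tags allowed rise with RAS tags, and the model put a larger share of its peaks at scores under 21 than the list has. The lower mean may come from that mix, so it does not settle whether the model matches the pile-up.

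At scores of 21 and over the same model put 309 candidates past the limit against 953 listed, the split at 21 being chosen after seeing the data, and this excess may mark sites with more HMGA1 in RAS cells. With an extra variation between libraries of 0.3 (coefficient of variation) it put 1532 past the limit there, and 5585 at scores under 21, far more than the 1399 listed. The larger count does not exclude this setting, because the model leaves out the filter on the local surroundings, which would lower its counts. Equal rates and a gain cannot be told apart for these peaks, because 1 library per group gives no measure of the variation between libraries. The lack of that filter bears on all counts of the model, which also takes the peak numbers as candidate ranks. The smallest exact conditional binomial p of any listed peak was 6.3e-07, and multiplied by 210296, the lower bound on candidates, it was 0.132. This p does not allow for the calling of candidates by their RAS tags, so the product only describes the list. A list called in the other direction, vector over RAS, would measure how many peaks this selection gives, and was not analysed here.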
